A study of Mus musculus with 4 samples.

How the data were processed

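Kidneys of 4 male mice, 2 controls and 2 Tcf21-KO, were minced and digested with liberase, hyaluronidase and DNase, then with trypsin, and strained, per the labels' protocols. For each library, 29000 cells were loaded on the GEM-X 3′ v4 kit of 10x Genomics, which tags the 3′ end of each transcript with a UMI, to recover 20000 cells, per the labels' protocols. The authors deposited whole-number UMI counts per gene and cell barcode, 1 matrix per library, with no normalization. The counts were made with Cell Ranger 8.0.0, per the file headers, whereas the submitters' processing notes list Cell Ranger 2.1.1 and the mouse build mm10. The annotation release and the filters on barcodes are not given in the sources used here. The matrices held 30569, 26928, 30297 and 31118 barcodes for control replicates 1 and 2 and Tcf21-KO replicates 1 and 2, above the targeted number, with at least 500 UMIs each in control replicates 1 and 2 and Tcf21-KO replicate 2 and 504 in Tcf21-KO replicate 1. Of 33696 genes listed, 31961 identifiers were found in GENCODE vM21 (GRCm38), which gave the position of Tcf21, and 1735 were not.

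Genotype and Cre status came from the labels. The numbers of the control replicates follow accession order and only name the samples, and the Cre status of the Tcf21-KO mice is not given in the sources used here. The mouse was the replicate, and cells were never treated as replicates.

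Cells with fewer than 500 genes or over 30% mitochondrial UMIs were left out. Doublets were scored with Scrublet per library, and the top 0.4% per 1000 barcodes were marked and left out, 11376 cells in all. Scrublet's automatic threshold would have marked 4.98% to 6.41%. This kept 85367 cells. Counts were scaled per cell and log-transformed, and 2000 variable genes (without mitochondrial, ribosomal protein, haemoglobin and sex-linked marker genes and Tcf21), 40 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 34 clusters. A cluster was named from markers fixed before the data were examined, when its mean marker score was at least 0.8 and 0.3 above that of the next class, and at least 3 markers were found in at least 20% of its cells. These 3 thresholds were set after the clusters were seen. Dividing cells and clusters with over 50% of cells marked as doublets stayed unnamed. This named 27 clusters and 77457 cells. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

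Counts were summed per library over the cells of each class with at least 20 cells in every library, which gave 15 classes, and over all kept cells. In each of these 16 fits, genotypes were compared by edgeR's quasi-likelihood test with TMM factors on genes kept by filterByExpr, with Benjamini-Hochberg adjustment within the fit and a threshold of 0.05. The adjustment did not run over the 16 fits together. The difference in Tcf21 between classes was tested as a class by genotype interaction with library as a block. The 25 gene lists, holding 421 genes and fixed before the data were examined, were tested where at least 3 members were measured, with camera at a preset correlation of 0.01 on log counts weighted by voom, and also with an estimated correlation and with fry. For counts adjusted over the list alone, Benjamini-Hochberg adjustment ran over the members of 1 list. Shares of cells were compared by an exact two-sided permutation test, whose smallest p is 0.333 with 2 mice per genotype.

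Genes were named by a rule fixed before the data were examined. It takes Tcf21 in the classes, and in podocyte-like and proximal tubule-like cells the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 20 CPM in the higher genotype and with both Tcf21-KO libraries on 1 side of both controls. In other classes it takes 3 each way, where none passed the 2 smallest p each way, and from each list at most 4 members past the threshold or the member with the smallest p. Where a genotype had 0 counts in both libraries, the fold is a bound from a floor of 3 counts over the group. Shares of cells with a Tcf21 UMI are also given after thinning each cell to 2000 UMIs. Genes whose reads could be shared with near-identical copies, or with overlapping genes, were not resolved further.

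The test was tried on simulated counts drawn from the real means and library sizes, with a common spread for all genes of a fit. Spreads that differ between genes and libraries that deviate together were left out, so recovery in the real data may be lower. In each fit 200 genes of at least 20 CPM were changed by 2, 4 or 8 times, and the test was then run. For podocyte-like cells (10063 genes) it recovered 8.96%, 74.6% and 98.5% of these with 4 false calls, for parietal epithelial-like cells (12140 genes) 7.46%, 68.7% and 98.5% with 7, for thick ascending limb-like cells (18375 genes) 2.99%, 59.7% and 100% with 7, and for proximal tubule-like cells (12620 genes) 8.96%, 98.5% and 100% with 4.

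Alternatives fixed before the data were examined were size factors by median of ratios, DESeq2, no filter on low counts, leaving out each library in turn, limits of 15% mitochondrial UMIs and 1000 genes per cell, keeping marked doublets, clustering at resolutions 0.5 and 2 or per library or without the genes called in podocyte-like cells, equal cell numbers, leaving out genes at least 10 times higher in another class, and shares of the cells that are not proximal tubule-like. Alternatives chosen after seeing the data were a limit of 50% mitochondrial UMIs, podocyte-like and parietal epithelial-like cells together, a term for 2 pairs of libraries that deviated together, leaving out clusters with over 95% of cells from Tcf21-KO, leaving out parietal sub-clusters led by proximal tubule genes (found at resolution 0.6), clustering without the genes called in any class, shares of named cells, and parietal sub-clusters led by proximal tubule genes counted as proximal tubule-like.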

Results

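Single-cell transcriptomes were measured in kidneys of 4 male mice aged 2 to 3 weeks on a mixed strain background. In 2 Tcf21-KO mice the transcription factor gene Tcf21 had been removed from podocyte precursors by a Cre recombinase under the control of Pax8, a gene of the nephron lineage. The 2 control mice were a Cre-negative animal (control replicate 1) and a Cre-positive animal (control replicate 2). Podocytes are the epithelial cells whose foot processes and slit diaphragms form the outer layer of the glomerular filter, and the series presents the deletion as a model of congenital nephrotic syndrome, in which that filter leaks protein from early life. The comparison asked how kidney cells, podocytes first, differed between the genotypes. Each library came from 1 mouse. The total was 307427457 and 254024242 unique molecular identifier (UMI) counts in control replicates 1 and 2, and 237361784 and 275423910 in Tcf21-KO replicates 1 and 2. The filters kept 20272 and 18954 control cells and 22326 and 23815 Tcf21-KO cells, with median depths of 10081, 10045, 7560.5 and 9271 UMIs per cell. Cell classes were rebuilt here from marker genes, so each is called "like" its type. Values in CPM are UMI sums over the cells of a class in 1 library, scaled to a common total. They were corrected for library composition unless raw values are named, and each error is the SD over 2 mice. Intervals per library cover counting error only.

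Tcf21 (ENSMUSG00000045680, GRCm38 chromosome 10, 22817281 to 22820174), a basic helix-loop-helix factor of podocytes and kidney stroma, was lower in podocyte-like cells of both Tcf21-KO libraries than in both controls. Raw values were 656 and 201 CPM in control replicates 1 and 2 (exact 95% Poisson intervals 623 to 691 and 180 to 223) against 53.3 and 8.19 in Tcf21-KO replicates 1 and 2 (43.8 to 64.3 and 3.29 to 16.9). A Tcf21 UMI was found in 91.2% and 70.7% of control podocyte-like cells and in 34.3% and 10.1% of Tcf21-KO cells, at median depths of 8014, 8185, 8548 and 12104 UMIs. In proximal tubule-like cells, which should lack the gene, the highest share in any library was 0.131%, at median depths of 5966, 6644.5, 4556.5 and 5738.5 UMIs. After each cell was thinned to 2000 UMIs, the podocyte-like shares were 63.2%, 31.8%, 9.45% and 0%, with 12, 9, 6 and 4 shallower cells left out. The last share is 0 of 65 cells, which allows a share of cells with a UMI of up to 4.62%. The control libraries differed from each other, and the fold change of -3.66 on the log2 scale (SE 0.91, n = 2 mice per genotype) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 10101 genes (adjusted p = 0.159). It passed without Tcf21-KO replicate 1 (-5.73) and without Tcf21-KO replicate 2 (-2.93), and also with no filter on low counts (-3.67) and with a term for the 2 library pairs, chosen after seeing the data (-3.89).

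The genotype difference in Tcf21 was not alike in the cell classes. Fibroblast-like cells held raw values of 292 and 98.6 CPM in the controls and 374 and 496 in the Tcf21-KO libraries, a log2 fold change of 1.01 (SE 0.59, adjusted p = 0.967 by edgeR's quasi-likelihood test). Mural and mesangial-like cells held 5.14, 4.99, 4.82 and 19.3 raw CPM, with a log2 fold change of 1.13. The log2 fold change in podocyte-like cells lay below that in fibroblast-like cells by a tested difference of -4.88 (SE 0.66, adjusted p = 0.00327 by edgeR's quasi-likelihood test of the interaction). It lay below that in mural and mesangial-like cells by -4.52 (SE 0.93, adjusted p = 0.0281 by the same test). In parietal epithelial-like cells, the flat cells that line Bowman's capsule, Tcf21 fell from 30.8 and 11.6 to 0.258 and 0.164 raw CPM (log2 fold change -6.44, SE 0.83, adjusted p = 0.0306 by edgeR's quasi-likelihood test). The control signal there rested on 24 and 10 UMIs and the Tcf21-KO signal on 1 and 1. The deleted part of the gene is not given in the sources used here, so UMIs from its 3′ end need not report the deletion itself.

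**Figure D1:**
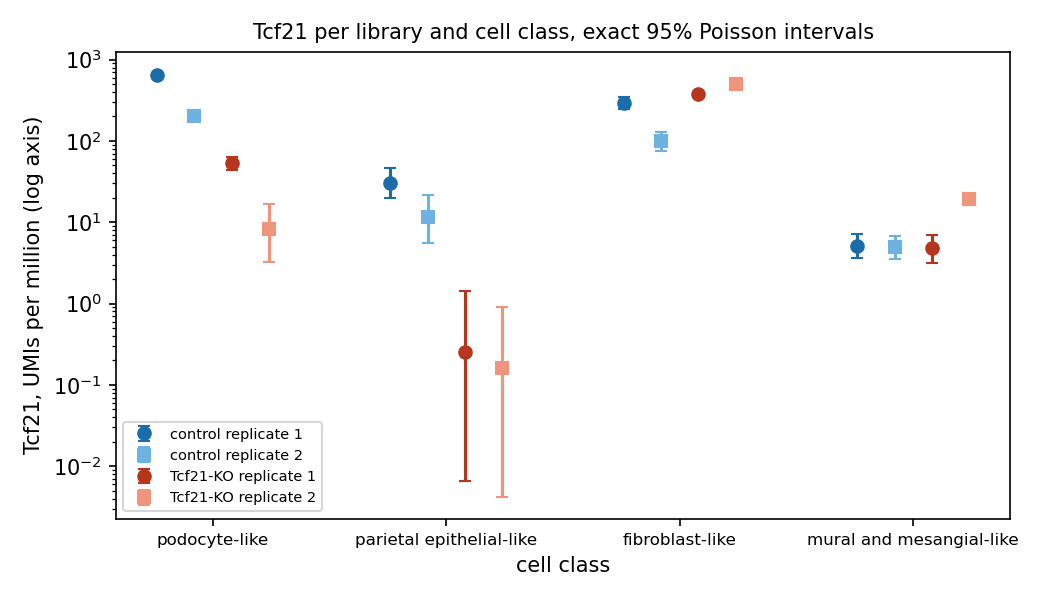
Tcf21 CPM (log axis) in each of the 4 libraries for podocyte-like, parietal epithelial-like, fibroblast-like and mural and mesangial-like cells, with exact 95% Poisson intervals that cover counting error. In podocyte-like cells both Tcf21-KO libraries (53.3 and 8.19) lie below both controls (656 and 201), while in fibroblast-like cells both lie above them.

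Podocyte-like cells of Tcf21-KO mice had 69 genes higher and 39 lower than those of controls. Rises included Crispld1 (ENSMUSG00000025776), which went from 0 to 23.7 and 45.0 normalised CPM in Tcf21-KO replicates 1 and 2 and was at least 38.2-fold higher, and Il20ra (ENSMUSG00000020007), a cytokine receptor subunit. Il20ra went from 0 to 24.5 ± 1.18 CPM and was at least 30.6-fold higher (floor of 3 counts over the control group). Igfbp2 (ENSMUSG00000039323) and Igfbp5 (ENSMUSG00000026185), which bind insulin-like growth factors, rose by 6.87 (SE 0.90) and 5.78 (SE 0.62) on the log2 scale, Igfbp5 from 3.25 ± 2.67 to 175.5 ± 77.8 CPM. Tppp3 (ENSMUSG00000014846), which promotes tubulin polymerisation, rose from 3.65 ± 1.30 to 211.8 ± 52.6 (5.85, SE 0.42). The homeobox gene Prrx1 (ENSMUSG00000026586) rose by 6.30, the potassium channel gene Kcnma1 (ENSMUSG00000063142) by 5.83, the protein kinase A subunit gene Prkar2b (ENSMUSG00000002997) by 5.52, Lrrc36 (ENSMUSG00000054320) by 5.31 and Plppr4 (ENSMUSG00000044667) by 5.09. Adjusted p-values of these 10 genes lay between 0.00768 and 0.0345 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with n = 2 mice per genotype. The naming rule itself required each gene to be higher in both Tcf21-KO libraries than in both controls.

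The falls included a collagen gene and the tau gene. Col1a2 (ENSMUSG00000029661), a chain of type I collagen, fell from 469.6 ± 45.5 to 2.76 ± 0.989 CPM (log2 fold change -7.48, SE 0.43, adjusted p = 0.00414 by edgeR's quasi-likelihood test). Mapt (ENSMUSG00000018411), which encodes the microtubule protein tau, fell from 833.3 ± 56.3 to 25.7 ± 16.8 (-4.96, SE 0.52). Loxl2 (ENSMUSG00000034205), an enzyme that crosslinks collagen, fell from 156.6 ± 99.5 to 0 and was at least 160.5-fold lower, by a floor of 3 counts over the Tcf21-KO group. Hs3st3a1 (ENSMUSG00000047759), which modifies heparan sulfate, changed by -7.45 (SE 0.43), and the disaccharidase gene Mgam (ENSMUSG00000068587) by -7.45 (SE 0.46). The log2 fold changes of R3hdml (ENSMUSG00000078949), Fam78b (ENSMUSG00000060568), Syt17 (ENSMUSG00000058420), the iron reductase gene Steap3 (ENSMUSG00000026389) and the homeobox gene Pknox2 (ENSMUSG00000035934) were -8.02, -7.01, -6.49, -5.38 and -4.86. Adjusted p-values of these 10 genes lay between 0.00414 and 0.0457 by the same test. Pooled over the libraries, fibroblast-like cells held the highest level of Col1a2, Loxl2, Steap3 and Pknox2 among the classes, and distal convoluted tubule-like cells that of Syt17.

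**Figure D2:**
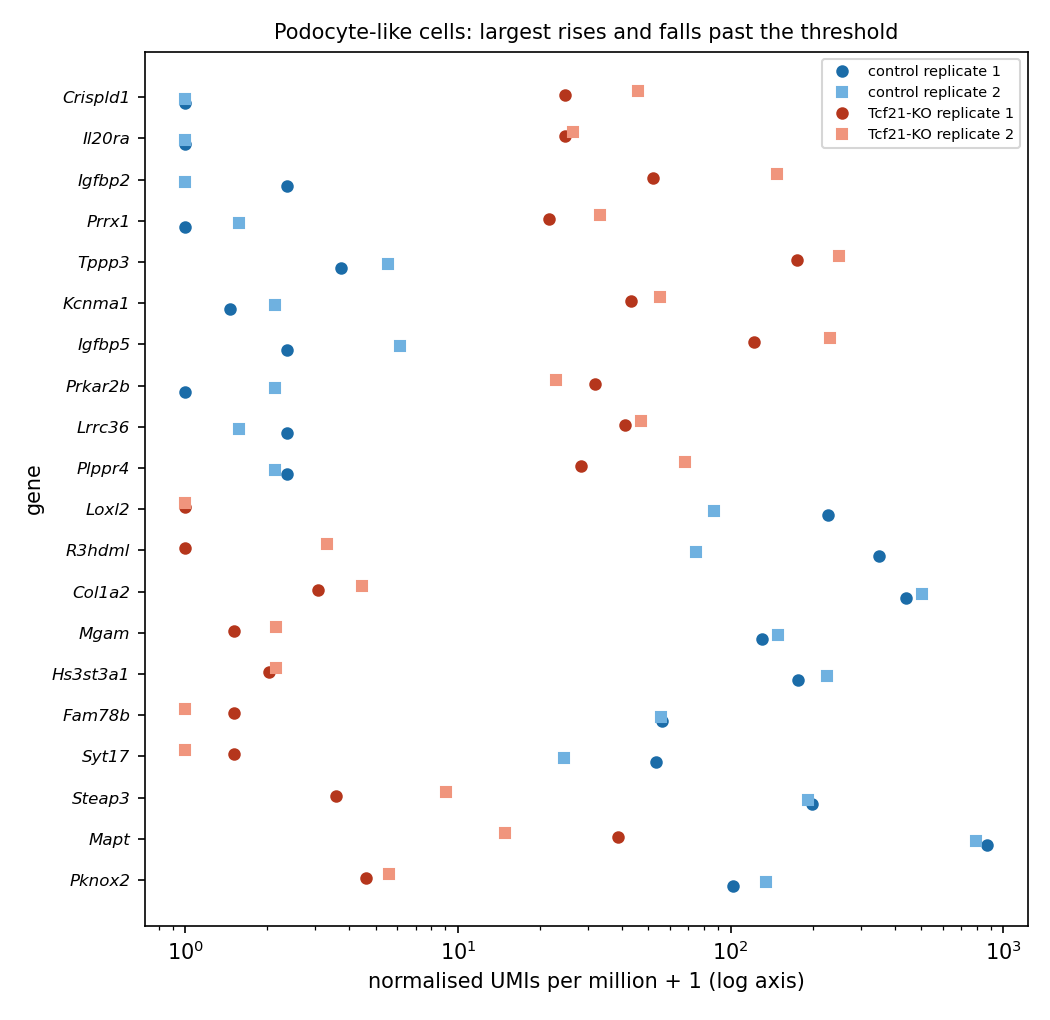
Normalised CPM plus 1 (log axis) of 20 genes that rose or fell past the threshold in podocyte-like cells of each library (1 point per mouse). For each gene both Tcf21-KO points lie on the same side of both control points, as the naming rule required. Col1a2 moved from a mean of 469.6 to 2.76 and Tppp3 from 3.65 to 211.8.

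Among the gene lists fixed for podocytes, 0 of 28 measured slit diaphragm and foot process genes passed over all genes and 1 passed adjusted over the list alone, Iqgap1, at 348.9 ± 24.9 and 1044 ± 25.0 CPM (log2 fold change 1.58, adjusted p = 0.0613 over all genes by edgeR). The list's median log2 fold change was 0.08 (camera, adjusted p = 0.663). A member looked at after its values were seen was the nephrin gene Nphs1, at 1205 ± 27.8 in controls and 1190 ± 203 in Tcf21-KO. Of 15 podocyte transcription factors 0 passed over all genes, and 1 rose and 1 fell adjusted over the list alone. Wt1, also named after its values were seen, held 1517 ± 289 and 1558 ± 136.3 CPM. Tubule injury genes were higher as a list (median 1.23 over 12 genes, camera, adjusted p = 0.000863; adjusted p = 0.862 with an estimated correlation), with 1 member up over all genes and 5 up and 1 down adjusted over the list alone. The member that passed was Il34, a ligand of the macrophage growth factor receptor, which rose from 50.8 ± 4.11 to 210.1 ± 10.9 (log2 fold change 2.05, adjusted p = 0.0245 by edgeR). Of 11 extracellular matrix genes Ccn2, a matrix signalling protein, rose from 497.1 ± 81.3 to 3992 ± 646 (log2 fold change 3.01, adjusted p = 0.0192 by edgeR) and Col1a2 fell, with 5 up and 1 down adjusted over the list alone (camera, adjusted p = 0.0502).

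Cholesterol synthesis genes were higher as a list in podocyte-like cells (median 0.52 over 17 genes, camera, adjusted p = 0.00164; adjusted p = 0.862 with an estimated correlation), with 0 members past the threshold over all genes by edgeR and 1 adjusted over the list alone, Fdft1, which makes squalene, at 23.1 ± 3.67 and 74.8 ± 14.8. Glomerular basement membrane genes were higher as a list (median 0.48 over 16 genes, camera, adjusted p = 0.0347; adjusted p = 0.862 with an estimated correlation), with 0 members up over all genes and 0 adjusted over the list alone. Inflammatory chemokine and cytokine genes were likewise higher (median 1.22 over 6 genes, camera, adjusted p = 0.0304; adjusted p = 0.862 with an estimated correlation), with 0 members up over all genes and 1 adjusted over the list alone, the chemokine gene Cxcl12 at 232.1 ± 29.5 and 764.9 ± 189.9. Cxcl12 held its direction in podocyte-like cells alone, and its log2 fold change was -0.17 when parietal epithelial-like cells were added to them. Slc12a1, the sodium transporter of the thick ascending limb, stood at 339.4 ± 130.3 CPM in control and 81.8 ± 13.1 in Tcf21-KO podocyte-like cells (log2 fold change -2.06, adjusted p = 0.0628 by edgeR). It is a marker used to name thick ascending limb-like cells, so these values need not reflect expression by podocytes. Free RNA or doublets as their source were not tested for this gene.

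The 69 and 39 genes were called among 10101 tested in podocyte-like cells, at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 974 genes, and DESeq2 called 222, of which 106 were shared. The test called 0 genes without control replicate 1 and 0 without control replicate 2, 707 without Tcf21-KO replicate 1 and 343 without Tcf21-KO replicate 2; a library left alone in its group was assumed to vary like those of the other genotype. It called 39 genes with the cells marked as doublets kept, 65 without genes at least 10 times higher in another class, 455 at a coarser clustering in which 33 of the 108 genes were shared, and 0 when each library was clustered on its own. These last 2 settings compared unlike cells, because their podocyte-like clusters took in parietal epithelial-like cells. The coarser cluster held 70.7% and 64.1% podocyte-like cells of the finer clustering in controls and 36.8% and 11.4% in Tcf21-KO replicates 1 and 2. With each library on its own, these shares were 100.0%, 63.3%, 99.0% and 11.4%.

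Parietal epithelial-like cells of Tcf21-KO mice had 162 genes higher and 37 lower of 12146 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (DESeq2 549). Without 1 sub-cluster, made up of Tcf21-KO cells only, 0 of 10916 genes passed and 879 had an unadjusted p under 0.05. No list held in the full class with an estimated correlation, while fry called 5. Krt20, a keratin of injured tubules and urothelium, went from 0 to 138.4 ± 32.3 CPM (at least 72.0-fold), Pmaip1, a pro-apoptotic target of p53, from 0 to 116.4 ± 32.1 (at least 67.0-fold) and Postn, a matrix protein, from 0 to 86.8 ± 20.7 (at least 45.2-fold). Besides Tcf21, the largest falls were in Col14a1 (log2 fold change -5.68, SE 0.72) and Alb (-4.99, SE 0.73). Of 13 genes of parietal and activated parietal cells 4 rose, Cd44 by 3.84, Vcam1 by 3.01, Cd9 by 2.86 and Sox9 by 3.43 on the log2 scale, with 8 up and 1 down adjusted over the list alone (camera, adjusted p = 1.38e-05; adjusted p = 0.310 with an estimated correlation). CD44 is a cell surface marker of activated parietal cells, and its transcript went from 30.7 ± 8.18 to 440.6 ± 31.8 CPM. Among 24 extracellular matrix genes Postn and the fibronectin gene Fn1 were among those that rose, with 5 up and 1 down adjusted over the list alone (camera, adjusted p = 0.00970; adjusted p = 0.310 with an estimated correlation).

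Of 15 proximal tubule transport genes 7 rose in parietal epithelial-like cells and 12 did adjusted over the list alone (camera, adjusted p = 5.32e-09; adjusted p = 0.310 with an estimated correlation). Among them were the bicarbonate cotransporter gene Slc4a4, from 32.1 ± 4.59 to 625.1 ± 91.9 CPM, and the glucose transporter gene Slc2a2, up by 5.58 on the log2 scale. Tubule injury genes rose in 6 of 23 cases, including the lipocalin gene Lcn2, a marker of tubular damage, by 4.89, with 16 up and 1 down adjusted over the list alone (camera, adjusted p = 4.47e-12; adjusted p = 0.310 with an estimated correlation). Of 9 iron, complement and phagocyte genes 5 rose, among them the complement gene C3 by 3.11, with 7 adjusted over the list alone (camera, adjusted p = 3.32e-08; adjusted p = 0.310 with an estimated correlation). Of 15 chemokine and cytokine genes 5 rose, with 8 up and 1 down adjusted over the list alone (camera, adjusted p = 0.000412; adjusted p = 0.310 with an estimated correlation). Of 18 glomerular basement membrane genes the basement membrane gene Nid2 and the angiopoietin gene Angpt1 fell, by -1.76 and -2.89, with 1 up and 9 down adjusted over the list alone (camera, adjusted p = 0.000786; adjusted p = 0.383 with an estimated correlation). A sub-cluster led by genes that include podocyte genes took a smaller part of the class in both Tcf21-KO libraries, and these falls were not tested apart from that change in makeup.

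The makeup of the parietal epithelial-like class differed between genotypes. Of its 6 sub-clusters, 1 led by the proximal tubule genes Cyp2j5 and Slc13a1 together with Krt20 and Pmaip1 held 0, 0, 133 and 203 cells in control replicates 1 and 2 and Tcf21-KO replicates 1 and 2. Another led by Fn1, Vcan and Postn held 2, 1, 101 and 82 cells. A further one led by genes that include the podocyte genes Nell2 and Ptpro held 49 and 32 of the 84 and 88 control cells and 24 and 84 of the 355 and 509 Tcf21-KO cells. Without the sub-cluster led by proximal tubule genes 0 genes passed edgeR's test, with 879 at an unadjusted p under 0.05, where the full class gave 199 and 2031, and DESeq2 gave 549. All cells of that sub-cluster were Tcf21-KO cells, so the loss of calls is no independent test, and Cd44, Sox9 and Fn1 then had log2 fold changes of 2.86, 3.03 and 3.46. The antigen presentation gene H2-Aa and the lipid carrier gene Apoe then had log2 fold changes of -0.87 and -0.34, against 2.78 and 1.89 in the full class. The count was also 0 without control replicate 1, without control replicate 2 and with marked doublets kept, 1344 without Tcf21-KO replicate 1 and 873 without Tcf21-KO replicate 2.

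Thick ascending limb-like cells, the salt-reabsorbing cells that made up 27.3% to 50.5% of each library, had 48 genes higher and 0 lower in Tcf21-KO of 18428 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (1974 at an unadjusted p under 0.05, 888 by DESeq2). Rises included Rerg (log2 fold change 9.03, SE 0.64), a small GTPase of the Ras family, Gabrp (7.99, SE 0.78), a subunit of a chloride channel gated by GABA, from 0.398 ± 0.336 to 104.7 ± 40.9 CPM, and Anxa3 (5.58, SE 0.34). Of 24 tubule injury genes 6 rose and 22 rose adjusted over the list alone, with a median log2 fold change of 3.19 (camera, adjusted p = 4.15e-27; adjusted p = 0.395 with an estimated correlation). The extracellular chaperone gene Clu rose from 10.8 ± 2.44 to 404.7 ± 29.8 CPM, the keratin gene Krt19 from 2.35 ± 0.484 to 72.1 ± 16.5 and the annexin gene Anxa1 from 7.11 ± 0.674 to 134.2 ± 29.3, each with an adjusted p of 0.0330 by edgeR. Anxa3 was a member too, and the remaining 2 past the threshold, Lcn2 and Cd44, were named after their values were seen. Of 14 parietal and activated parietal genes 2 rose, Krt19 and Cd44, and 10 rose adjusted over the list alone (camera, adjusted p = 5.67e-08; adjusted p = 0.395 with an estimated correlation). Of 24 extracellular matrix genes Sparc rose by 4.01 and 6 rose adjusted over the list alone (camera, adjusted p = 5.37e-11; adjusted p = 0.395 with an estimated correlation).

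**Figure D3:**
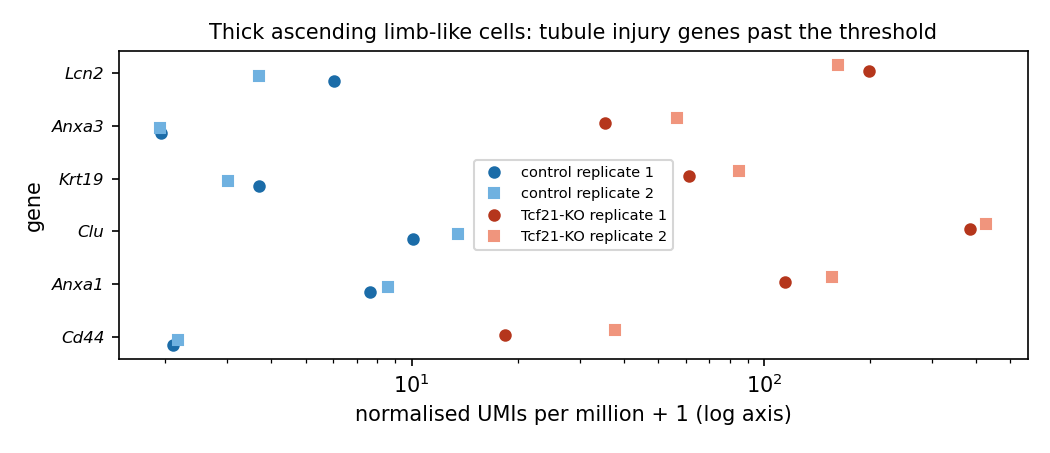
Normalised CPM plus 1 (log axis) of the 6 tubule injury genes past the threshold in thick ascending limb-like cells of each library (1 point per mouse). Both Tcf21-KO points lie above both control points for each gene; Clu moved from a mean of 10.8 to 404.7.

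These thick ascending limb-like differences went in part with 1 cluster, led by Gabrp, that held 0.0197% and 0.0475% of control cells and 7.83% and 7.83% of Tcf21-KO cells. Clustering without the 350 genes called in any class gave it again, with 7, 11, 1761 and 1853 cells in control replicates 1 and 2 and Tcf21-KO replicates 1 and 2, but its marker score was then too low for a class name. In the main clustering its score was 0.85, just above the threshold of 0.8 set after the clusters were seen. The other clusters of the class scored 1.18 to 1.54, so its class name is less sure than theirs. Some other clusters of the class differed between libraries of 1 genotype, such as a cluster with 16.0% and 0.559% of the control cells and 12.7% and 0.143% of the Tcf21-KO cells. Transcripts encoded by mitochondria were lower as a list (median -0.71 over 12 genes, camera, adjusted p = 0.000276; adjusted p = 0.581 with an estimated correlation). Tcf21-KO replicate 2 had the lowest level of each, while Tcf21-KO replicate 1 lay between the controls for 8 of the 12. Digestion stress genes were higher (median 0.75 over 20 genes, camera, adjusted p = 1.24e-07; adjusted p = 0.395 with an estimated correlation), with 1 member, the heat shock gene Hspb1, up by 2.84 over all genes and 1 adjusted over the list alone. Without the Gabrp cluster, removed because over 95% of its cells came from Tcf21-KO, edgeR called 0 genes in this class, with 583 at an unadjusted p under 0.05. The genotype itself sets this choice of cells, so the loss of calls is no independent test, and the log2 fold changes of Rerg, Gabrp and Clu were then 4.90, 3.98 and 2.17. The test over all cells of the class also called 0 without control replicate 1 and 0 without control replicate 2, 1358 without Tcf21-KO replicate 1, 614 without Tcf21-KO replicate 2 and 283 when cells were limited to 15% mitochondrial UMIs.

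In proximal tubule-like cells, which take up filtered protein, glucose and salt, 0 of 12640 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 486 at an unadjusted p under 0.05 and 17 called by DESeq2. The gene with the smallest p was C3 (ENSMUSG00000024164), at 1.56 ± 1.10 CPM in controls and 63.9 ± 15.7 in Tcf21-KO (log2 fold change 5.40, SE 0.47, adjusted p = 0.327 by edgeR). Fgb (ENSMUSG00000033831), a fibrinogen chain, had a log2 fold change of 4.69, Adgrb3 (ENSMUSG00000033569) of -3.21 and Hpd (ENSMUSG00000029445), an enzyme of tyrosine breakdown, of -2.42. Of 19 tubule injury genes 0 passed over all genes and 12 rose adjusted over the list alone (median 2.05, camera, adjusted p = 8.60e-18; adjusted p = 0.297 with an estimated correlation). For 9 chemokine and cytokine genes the same counts were 0 and 5 (median 1.73, camera, adjusted p = 4.85e-05; adjusted p = 0.297 with an estimated correlation). Transport genes had a median of -0.07 over 21 genes, with 0 past the threshold by either count (camera, adjusted p = 0.221). The sub-cluster of parietal epithelial-like cells led by proximal tubule genes (133 and 203 cells in Tcf21-KO replicates 1 and 2) was not in this fit. The fit was not repeated with those cells added. EdgeR called 472 genes without Tcf21-KO replicate 1, 6 without Tcf21-KO replicate 2 and 226 with no filter on low counts.

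Among the 11 remaining classes 0 genes passed edgeR's quasi-likelihood test, while DESeq2 called 681 in all, of which 259 in intercalated-like, 142 in mononuclear phagocyte-like and 59 in fibroblast-like cells. At an unadjusted p under 0.05 edgeR had 1032, 1410 and 631 genes in these 3 classes. The genes with the smallest p in intercalated-like cells, the acid-base transporting cells of the collecting duct, were the interferon-induced gene Oasl2 (log2 fold change 5.81, SE 0.48) and the mucin gene Muc4 (4.39, SE 0.36), with an adjusted p of 0.248 by edgeR. Among named genes higher in Tcf21-KO, Fgf13 (4.99, SE 0.61) and the integrin gene Itgax (2.59, SE 0.32) led in mononuclear phagocyte-like cells, with an adjusted p of 0.276 by edgeR. In fibroblast-like cells Spon1 (3.30, SE 0.38), a matrix protein, led the rises, with an adjusted p of 0.279 by edgeR. Genes lower in Tcf21-KO had smaller p, Ikzf3 (-3.557) in mononuclear phagocyte-like cells and Acsm2 (-6.26, adjusted p = 0.1875 by edgeR) in fibroblast-like cells. EdgeR called 6593 genes over these 11 classes without Tcf21-KO replicate 1 and 667 without Tcf21-KO replicate 2. The principal and connecting-like class held a cluster, led by Aqp2 and Aqp4, with 0% (exact 95% binomial interval up to 0.0182%), 0.137%, 0.237% and 15.1% of the cells of control replicates 1 and 2 and Tcf21-KO replicates 1 and 2, so its values in the last library came mostly from that cluster.

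Over all 16 fits, camera with a preset correlation placed 162 of 387 list tests past an adjusted p of 0.05, 113 up and 49 down in Tcf21-KO. With an estimated correlation, which 4 libraries estimate only roughly, 0 held, the smallest adjusted p being 0.227. The fry test called 6, of which 5 were in parietal epithelial-like cells. Tubule injury genes were up in 13 of the 16 fits, extracellular matrix genes in 12 and chemokine and cytokine genes in 11, digestion stress genes were up in 8 and down in 2, while transcripts encoded by mitochondria were down in 11. The smallest adjusted p-values with an estimated correlation were 0.242, 0.310, 0.239, 0.239 and 0.227 for these 5 lists. The 16 fits share the same 4 libraries, so these counts are not independent. The median mitochondrial share of all barcodes was 18.65% and 12.59% in control replicates 1 and 2 and 12.88% and 2.97% in Tcf21-KO replicates 1 and 2. Only Tcf21-KO replicate 2 lay below both controls, so the mitochondrial count may rest largely on that library.

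Fibroblast-like, parietal epithelial-like and mononuclear phagocyte-like cells took larger shares of both Tcf21-KO libraries. Fibroblast-like cells made up 0.192% ± 0.0488 of control cells and 1.23% ± 0.554 of Tcf21-KO cells, 6.41 times as much, parietal epithelial-like cells 0.439% ± 0.0353 and 1.86% ± 0.387, and mononuclear phagocyte-like cells 1.79% ± 0.291 and 6.01% ± 0.762 (SD, n = 2). The log2 ratio of mononuclear phagocyte-like cells, 1.74, ran from 1.39 with at most 15% mitochondrial UMIs to 2.55 with each library clustered on its own. T and NK-like cells stood at 1.43% ± 0.105 and 2.38% ± 0.256. Both Tcf21-KO libraries also lay above both controls for neutrophil-like cells (0.428% ± 0.201 and 0.892% ± 0.437). The same held for intercalated-like (3.31% ± 1.34 and 5.39% ± 0.793) and endothelial-like cells (2.58% ± 0.667 and 3.47% ± 0.232). Distal convoluted tubule-like cells, which take up sodium chloride downstream of the thick ascending limb, stood at 11.8% ± 4.53 and 5.53% ± 3.63, and proximal tubule-like cells at 3.78% ± 0.367 and 2.59% ± 1.21. The exact two-sided permutation p of each was 1 in 3, the smallest that 2 against 2 mice allow. In distal convoluted tubule-like cells the genotypes overlapped at a coarser clustering (8.90% and 15.3% against 10.4% and 3.94%), at a finer one (9.72% and 15.8% against 11.7% and 5.39%) and with each library on its own (8.60% and 14.1% against 12.4% and 5.53%). An unnamed cluster that scored highest for distal convoluted tubule, close to another class, held 2.96% and 2.33% of control and 6.35% and 5.72% of Tcf21-KO cells. Counting the sub-cluster led by proximal tubule genes as proximal tubule-like, a choice made after seeing the data, left parietal epithelial-like cells at 0.414% and 0.464% of control and 0.994% and 1.28% of Tcf21-KO cells. Proximal tubule-like cells then overlapped between genotypes, at 3.52% and 4.04% against 2.32% and 4.30%. Podocyte-like cells made up 1.01% and 0.828% of the controls and 0.927% and 0.290% of Tcf21-KO replicates 1 and 2 (exact 95% binomial intervals 0.878 to 1.16, 0.704 to 0.968, 0.806 to 1.06 and 0.226 to 0.366). Their log2 ratio of -0.60 became -1.67 without Tcf21-KO replicate 1 and 0.01 without Tcf21-KO replicate 2, while a coarser clustering merged them with parietal epithelial-like cells. Podocyte-like and parietal epithelial-like cells together made up 1.43%, 1.29%, 2.52% and 2.43%. Of these 562 and 578 cells in Tcf21-KO replicates 1 and 2, 133 and 203 belonged to the sub-cluster led by proximal tubule genes. That sub-cluster held 0 cells of either control, so part of the larger total came from it. Fibroblast-like cells had a log2 ratio of 2.68, and 2.13 without Tcf21-KO replicate 2.

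Shares count cells that came through the digestion, the droplet capture and the filters, and the filters removed 5439 and 2891 control barcodes and 3188 and 1285 Tcf21-KO barcodes for over 30% mitochondrial UMIs. The median mitochondrial share of all barcodes was 18.65%, 12.59%, 12.88% and 2.97%. Unnamed clusters, kept out of the classes by thresholds set after the clusters were seen, took 5.21% ± 1.09 of control cells and 12.6% ± 3.37 of Tcf21-KO cells.

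**Figure D4:**
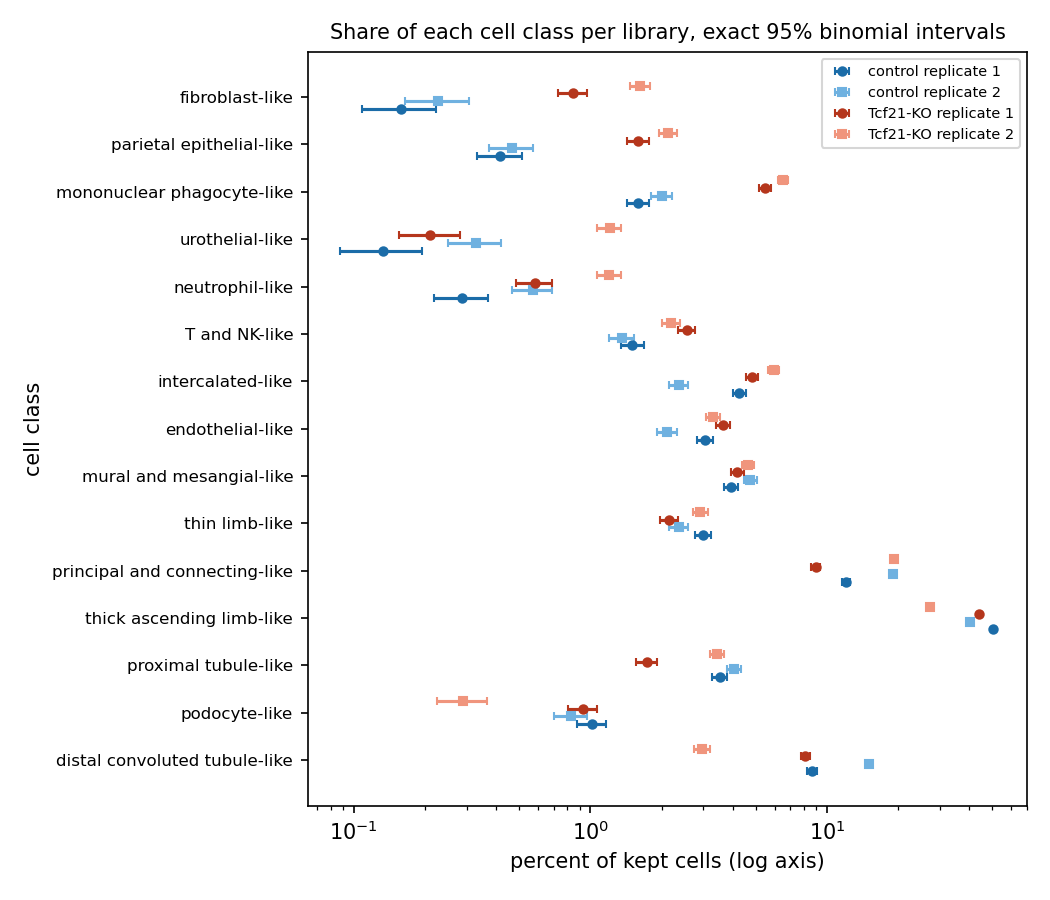
Percent of kept cells (log axis) in each of 15 named classes for the 4 libraries, with exact 95% binomial intervals that cover counting error. Fibroblast-like, parietal epithelial-like and mononuclear phagocyte-like cells have both Tcf21-KO points above both control points, with mean shares of 1.23%, 1.86% and 6.01% against 0.192%, 0.439% and 1.79%.

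In whole libraries, summed over all kept cells, 0 of 22594 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (2059 at an unadjusted p under 0.05, 817 by DESeq2). Gabrp came closest, at 0.641 and 40.6 mean CPM (log2 fold change 5.98, SE 0.25, adjusted p = 0.0623 by edgeR), followed by Mgl2, a lectin of macrophages, with a log2 fold change of 3.63. Tcf21 had a log2 fold change of 0.22 (SE 0.71, adjusted p = 0.948 by edgeR), which was -0.45 without control replicate 2, -0.35 without Tcf21-KO replicate 2 and -0.26 when cells were limited to 15% mitochondrial UMIs. EdgeR called 1749 genes without Tcf21-KO replicate 1 and 549 without Tcf21-KO replicate 2.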

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

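The second Tcf21 comparison, with mural and mesangial-like cells, was planned before the data were examined, while the shares of unnamed clusters and the clustering without called genes were looked at after the clusters were seen.

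The change in Tcf21 differed between cell classes by a test of the difference itself. The log2 fold change in podocyte-like cells was lower than in fibroblast-like cells by a difference of -4.88 (SE 0.66, adjusted p = 0.00327 by edgeR's quasi-likelihood test of the interaction, 279 of 11920 genes past the threshold). It was lower than in mural and mesangial-like cells by a difference of -4.52 (SE 0.93, adjusted p = 0.0281 by the same test, 288 of 13145 genes past the threshold). Both Tcf21-KO libraries lay below both controls in podocyte-like cells.

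Of the 7 unnamed clusters, which no comparison between classes used, 3 had larger shares in both Tcf21-KO libraries than in both controls. Cluster 8, led by the distal genes S100g, Trpv5, Klk1 and Calb1, held 2.96% and 2.33% of control cells and 6.35% and 5.72% of Tcf21-KO cells, a Tcf21-KO mean of 6.03%. Cluster 25 scored highest for B and plasma cells and was led by the dendritic cell genes Xcr1, Clec9a and Irf8, by Btla and by the B cell gene Ighm, so it may hold both cell types. It held 0.257% and 0.327% of control cells and 0.923% and 1.78% of Tcf21-KO cells, a Tcf21-KO mean of 1.35%. Cluster 6, led by the cell cycle genes Top2a, Cdk1 and Mki67, held 0.0740% and 0.142% of control cells and 0.179% and 0.890% of Tcf21-KO cells, a Tcf21-KO mean of 0.535% that rested mostly on Tcf21-KO replicate 2. With clustering that left out the 350 genes called in any class, the cluster that took most of its cells from cluster 8 held 2.93%, 2.33%, 6.32% and 5.71% of control replicates 1 and 2 and Tcf21-KO replicates 1 and 2, and the one from cluster 25 held 0.261%, 0.343%, 0.918% and 1.79%. No cluster then drew more cells from cluster 6 than from any other, and the cluster of dividing cells held 1.21%, 1.01%, 1.55% and 1.41%. The exact two-sided permutation p of the share of each of the 3 clusters was 1 in 3, the smallest that 2 against 2 mice allow.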

How the results depend on the processing

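No paired analysis was possible because the numbers of the control replicates follow accession order and only name the samples, so the labels give no pairs. The library pairs below were read from the expression values, and a fit with a term for them is no paired design. Settings chosen after seeing the data were a term for the library pairs (control replicate 1 with Tcf21-KO replicate 1, and control replicate 2 with Tcf21-KO replicate 2, which deviated together), a limit of 50% mitochondrial UMIs, podocyte-like and parietal epithelial-like cells together, the removal of clusters and sub-clusters, clustering without genes called in any class, shares of named cells, and parietal sub-clusters counted as proximal tubule-like. Leaving out a library leaves 1 mouse in its genotype, which is assumed to vary like the other genotype. With 2 mice per genotype and 69 to 207 podocyte-like cells per library, low genes and small differences were out of reach. The cause of the movements below was not tested unless a smaller set of cells or genes is named. Among 196 named gene results, 2609 values under other settings gave 2018 of the same direction and side of the threshold, 270 that lost the threshold, 307 that gained it and 14 of the other direction. Among 41 gene list results, 146 of 246 values held and 100 lost the threshold.

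Counts of genes past the threshold by edgeR, leaving out 1 library at a time, ran from 0 to 707 in podocyte-like cells (108 with all libraries), 0 to 1344 in parietal epithelial-like (199), and 0 to 1358 in thick ascending limb-like (48). They ran from 0 to 472 in proximal tubule-like (0), 0 to 6593 in the sum of the 11 remaining classes (0) and 0 to 1749 in whole libraries (0). DESeq2 called 222, 549, 888, 17, 681 and 817 genes in this order. With no filter on low counts there were 583 in podocyte-like, 1354 in parietal epithelial-like, 226 in proximal tubule-like cells, 2671 in the remaining classes and 1 in whole libraries. With the term for the library pairs there were 403 in podocyte-like, 549 in parietal epithelial-like, 417 in thick ascending limb-like cells, 66 in the remaining classes and 99 in whole libraries. With marked doublets kept there were 39 in podocyte-like and 0 in parietal epithelial-like cells. A limit of 15% mitochondrial UMIs gave 283 in thick ascending limb-like cells and 1 in whole libraries, and at least 1000 genes per cell gave 1 in the remaining classes. In podocyte-like cells, Leiden resolution 0.5 gave 455 and clustering each library separately 0, both with parietal epithelial-like cells merged in, most of all in Tcf21-KO replicate 2. Equal cell numbers gave 48 (fewer cells), podocyte-like and parietal epithelial-like cells together 507, and leaving out genes 10 times higher in another class 65 (fewer genes). Without sub-clusters led by proximal tubule genes, all Tcf21-KO cells, parietal epithelial-like cells gave 0, and without clusters over 95% Tcf21-KO, a choice the genotype sets, thick ascending limb-like cells gave 0. Of the list tests, 0 held with an estimated correlation and 6 were called by fry, against 162 by camera with the preset correlation.

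Tcf21 in podocyte-like cells (-3.66) passed the threshold with no filter (-3.67) and with the library pairs (-3.89). It ran from -5.73 to -2.51 without 1 library and passed without either Tcf21-KO library. Log2 fold changes that turned direction, none of them past the threshold except Apoe and H2-Aa with all cells, were Apoe (-0.34) and H2-Aa (-0.87) in parietal epithelial-like cells without sub-clusters led by proximal tubule genes, Cxcl12 in podocyte-like cells at resolution 0.5, which merges parietal epithelial-like cells in (-0.18), and with parietal epithelial-like cells (-0.17), Sdf2l1 in the same settings (-0.09 and -0.08), and Tcf21 in whole libraries at 15% mitochondrial UMIs (-0.26). Others turned without 1 library, with ranges of -0.04 to 3.43 for Gbp2, -0.49 to 0.09 for Mapt and -1.53 to 0.25 for mt-Atp8 in proximal tubule-like cells, -1.08 to 0.03 for mt-Atp8 in parietal epithelial-like cells, -0.00 to 1.72 for Tcf21 in mural and mesangial-like cells and -0.45 to 1.47 for Tcf21 in whole libraries.

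Log2 ratios of shares, Tcf21-KO over control, moved by more than the spread between mice as follows. With at most 15% mitochondrial UMIs they were 0.38 for T and NK-like, 0.05 for endothelial-like, 1.39 for mononuclear phagocyte-like, -0.31 for mural and mesangial-like, 1.65 for parietal epithelial-like and -0.50 for thin limb-like cells, and at most 50% gave 2.37 for mononuclear phagocyte-like cells. With each library clustered separately they were 1.73 for endothelial-like, 3.60 for fibroblast-like, 2.55 for mononuclear phagocyte-like and 0.58 for podocyte-like cells. Of these, the endothelial-like and fibroblast-like values rest on clusters of control replicate 1 that stayed unnamed and so gave 0%, and the podocyte-like value includes parietal epithelial-like cells. Resolution 0.5 gave 0.89 for podocyte-like cells, merged with parietal epithelial-like cells, and resolution 2 gave 2.50 for mononuclear phagocyte-like cells, which had 2.24 without the genes called in podocyte-like cells. At resolution 2, without those genes and at 50% mitochondrial UMIs, a mononuclear phagocyte cluster led by Lyz2 stayed unnamed, close to another class. A cluster with like leading genes was named in the main clustering. It held 0.6955% and 0.7228% of control and 0.9093% and 0.2561% of Tcf21-KO cells. For parietal epithelial-like cells marked doublets kept gave 1.85, and sub-clusters led by proximal tubule genes counted as proximal tubule-like 1.38. Without 1 library the ranges were -2.00 to -0.55 for distal convoluted tubule-like, 0.19 to 0.72 for endothelial-like, 2.13 to 3.08 for fibroblast-like, 0.34 to 1.19 for intercalated-like, and 1.86 to 2.28 for parietal epithelial-like cells. They were -1.67 to 0.01 for podocyte-like, -0.79 to 0.31 for principal and connecting-like, -1.13 to -0.14 for proximal tubule-like, -0.73 to -0.04 for thick ascending limb-like and -0.13 to 2.41 for urothelial-like cells.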

Other observations

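Tests chosen after the values they measure were seen were those of free RNA in podocyte-like and thick ascending limb-like cells, of urothelial-like cells, of strain sequence in other classes, of sequencing depth and of digestion stress between libraries, the count near Tcf21 by Fisher's exact test, and the rule that a bound on a median counts only if the upper quartile of its members meets it too.

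In intercalated-like cells tubule injury genes stood higher in Tcf21-KO as a list, with a median log2 fold change of 2.58 over 22 genes (camera, adjusted p = 7.88e-17, and 0.353 with an estimated correlation). By edgeR 0 members passed over all genes and 17 adjusted over the list alone. Over all genes of intercalated-like cells edgeR called 0, with 1032 at unadjusted p < 0.05 and 259 by DESeq2, and in mononuclear phagocyte-like cells 0, 1410 and 142. In the intercalated-like cells the chaperone gene Clu of this list stood at 63.8 and 46.8 CPM in control replicates 1 and 2 and at 669.2 and 866.4 in Tcf21-KO replicates 1 and 2. Interferon response genes of intercalated-like cells had a median of 2.84 over 16 genes, with 0 past the threshold over all genes and 8 adjusted over the list alone (camera up, adjusted p = 1.51e-11, and 0.353 with an estimated correlation). Those of mononuclear phagocyte-like cells had a median of -1.29 over 18 genes, with 0 and 4 by the same counts (camera down, adjusted p = 3.76e-08, and 0.710 with an estimated correlation). The difference between these classes was not tested. Principal and connecting-like cells carried the lipocalin gene Lcn2 at 87.8 ± 2.46 and 323.9 ± 25.1 CPM, with a log2 fold change of 1.88 that did not pass over all genes (adjusted p = 0.675 by edgeR).

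Cell division genes of mononuclear phagocyte-like cells had a median log2 fold change of 1.70 over 22 genes, with 0 past the threshold over all genes by edgeR and 17 adjusted over the list alone (camera up, adjusted p = 6.01e-16, and 0.710 with an estimated correlation). In whole libraries the class II antigen presentation gene H2-Ab1 stood at 35.8 ± 5.97 and 235.2 ± 42.9 CPM and the complement gene C1qa of macrophages at 16.9 ± 0.986 and 82.5 ± 4.05, both with an adjusted p of 0.173 by edgeR. Some transcripts led by other cells had lower values in Tcf21-KO libraries. In fibroblast-like cells the proximal tubule gene Acsm2 stood at 58.4 and 0.685 mean CPM and the collecting duct gene Fxyd4 at 89.0 and 5.02, and in endothelial-like cells the proximal tubule gene Kap at 25.2 and 4.22, none of them past the threshold by edgeR.

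The first pattern weighed is the set of 108 genes called in podocyte-like cells. For Col1a2 the tables argue against stromal cells or free RNA as the source of the control signal. Col1a1, Col3a1, Dcn and Lum UMIs per Col1a2 UMI in control podocyte-like cells were 0.00294 of that ratio in fibroblast-like cells. The 39 lower genes had a median log2 ratio of 5.24 in controls over the median of the other classes. This argues against free RNA spread over all classes, but it cannot exclude a source in a single class. Of the 39 genes, 22 had their highest control level in podocyte-like cells. Strain sequence carried along with the Tcf21 allele on this mixed background cannot be told apart: 3.74% of the calls with a position (4 of 107) lay within 10 Mb of Tcf21, against 0.569% of the genes tested (exact two-sided Fisher p = 0.0032), between the bounds of 3% and 10% set beforehand. These calls were Il20ra, Ccn2, Eya4 and Gm20125, with a median log2 fold change of 0.16 over 6 values in fibroblast-like, mural and mesangial-like and endothelial-like cells (upper quartile 0.53, bound 0.5), while Eya4 had 3.79 in thick ascending limb-like and 1.75 in thin limb-like cells and Ccn2 2.55 in urothelial-like cells. A candidate explanation is the loss of Tcf21 in the podocyte lineage, as a hypothesis, with the strain of the 4 genes near it open and no test of free RNA for the 69 higher genes, while 8 of the 10 rises named had their highest level, pooled over the libraries, in another class.

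The second pattern is the set of 48 genes higher in Tcf21-KO thick ascending limb-like cells, which went in part with 1 cluster, since without it Rerg, Gabrp and Clu had log2 fold changes of 4.90, 3.98 and 2.17, none past the threshold. The tables argue against free RNA, since the median of these genes lay above other thick ascending limb-like cells by log2 values of 3.83 and 3.45 within Tcf21-KO replicates 1 and 2, and against joined urothelial-like cells, whose markers stood at 6.4e-05 of the level Gabrp needs, with Gabrp at 379.0 CPM in the cluster and 52.4 in urothelial-like cells. Stress of digestion cannot be told apart, since the median of the digestion stress genes lay higher in the cluster by 0.90 and 1.32, on either side of the bound of 1. An injured state of the thick ascending limb in Tcf21-KO kidneys may be what the cluster holds, as a hypothesis with digestion stress open. The Cre-positive control, 1 mouse, had 0.0475% of its cells in the cluster, and the design does not separate a response to glomerular disease from a direct effect of the deletion in tubule cells, which Pax8 also marks.

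The third pattern is that control replicate 1 and Tcf21-KO replicate 1 deviated together from their genotypes' means, with correlations across genes, which are not independent replicates, of 0.29 to 0.74 over the 16 fits (0.46 in podocyte-like and 0.62 in thick ascending limb-like cells). For whole libraries the tables argue against depth. Replicate 1 over 2 had a log2 ratio of total UMIs of -0.21 in Tcf21-KO and 0.28 in controls. They cannot decide for depth within classes, where this test was not run. Podocyte-like cells summed to 2222444 and 1711152 UMIs in control replicates 1 and 2, and 2063075 and 855247 in Tcf21-KO replicates 1 and 2. The direction was shared in most classes, thick ascending limb-like cells included, and opposite in others such as endothelial-like cells. For cells with many mitochondrial UMIs, the median correlation over 15 classes was 0.54 with all cells and 0.54 without cells over 15%. That limit removed few cells in many classes, such as 618 to 599 endothelial-like cells in control replicate 1 (correlation 0.74 with all cells). This argues against such cells as the source in classes like these. It cannot decide for thick ascending limb-like cells (10238 to 2821 in that library), whose correlation under the limit was not looked at alone. Stress of digestion cannot be told apart: the list's median difference was -0.69 in Tcf21-KO and -0.19 in controls, inside the bound of 0.2, but the size of the control difference had an upper quartile of 0.52 over classes. A shared day or litter could lie behind the pairs, which no label gives, and no biological explanation was tested. The term for the pairs, chosen after seeing the data, moved the count in podocyte-like cells from 108 to 403.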
